A study of Mus musculus with 8 samples.

How the data were processed

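RNA of mouse morulae at embryonic day 3.0 was measured on 8 one-colour arrays, 3 from embryos injected with control siRNA (siControl) and 5 from embryos injected with siRNA against P150 (P150KD), with 10 embryos per array. Per the labels, total RNA went through 2 rounds of linear amplification before labelling, and an equal mass was labelled for each array, so all levels are relative and a change of total RNA per embryo is not measured. Per the file headers, the authors read the scans with Agilent Feature Extraction 10.5.1, and the processed signal is an intensity, background-subtracted and spatially detrended but not normalized between arrays. Per the file headers, the median spot and background signals are raw intensity values, and the remaining columns used are 0 or 1 flags of other kinds. The deposited series table holds log2 values; checked against the scanner files, they are log2 processed signals scaled to each array's 75th percentile and centred on each probe's median over the 8 arrays.

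The files held 59305 spots for 55681 probes, control spots left out. Spots of 1 probe were averaged, without spots called non-uniform or outlying where another remained. Signals were put on the log2 scale and the 75th percentile of each array was subtracted. The 75th percentile of the processed signal was 1336, 1344 and 986 on siControl replicates 1 to 3 and 1270, 1243, 1354, 1274 and 1539 on P150KD replicates 1 to 5. A probe was tested where it was well above background on at least 3 of the 8 arrays, whatever their group, which left 30348 probes. The number of arrays limits the precision of each value.

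The files hold no gene names, so probes were named by joining their RefSeq accessions to the RefSeq gene table: 27235 probes received 1 of 20660 symbols, 1450 RefSeq accessions had no match, and 16194 probes for genomic intervals and 10802 others stayed unnamed. Without descriptions the planned text search for retrotransposon probes could not be used: its hits were genes that share the abbreviation IAP, and probes of retrotransposons were not analysed here.

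P150KD was compared with siControl probe by probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. For counts of genes and for gene lists, the tested probe with the highest mean signal stood for its gene. The 20 gene lists were tested against all other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation; fry, which asks whether a list's genes move without comparing them with other genes, was an alternative. Counts are also given adjusted over the list alone. Where no array of a group was well above background for a probe, the fold is a nominal lower bound, set by the lowest signal that counted as well above background on each array. Some probes that did not count read above that signal, and their own signal was then used. List medians were also set against 10000 random lists matched on mean level, and a list of 15 leukocyte markers was added after the main values were seen. The arrays were also split into 3 and 5 in all 56 ways, the real one included.

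The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Chaf1a, the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap, up to 4 members of each list with the smallest p, and a set of stage and lineage genes. Since most of the largest changes reached the floor, a selection of genes measured in both groups was added after the values were seen. Zscan4d, one of the fixed genes, had no named probe and was not analysed here.

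Alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median, the series table, no filter on dim probes, only probes above background on all 8 arrays, the replicate number as a block, eBayes with trend and robust, array weights, the mean of all probes of a gene, and leaving out each array in turn. Normexp was run on the median spot signal, because the files hold no mean. All arrays lie on 1 slide with 1 scan date, so the planned slide block was not run. After the data were seen, the column of the slide as a block and scaling to the housekeeping list were added; 1 column holds the 3 controls and P150KD replicate 1, the other P150KD replicates 2 to 5.

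The procedure was tested on simulated data with 30348 probes. Of 100 probes changed 2-fold, 0 were recovered, though 94% had the right direction. Of 100 changed 4-fold, 29 were recovered, with 4 false calls. No other probes were changed, a far smaller share than the 13.9% called in the data. The adjustment recovers fewer probes where few change, so these recoveries do not carry over to the data. Array weights used statmod 1.5.0. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.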

Results

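Gene expression was measured on one-colour microarrays in mouse morulae at embryonic day 3.0, the compacting embryo shortly before the blastocyst forms. The embryos came from in vitro fertilisation and had been injected at the zygote stage with siRNA against P150, the large subunit of the histone chaperone CAF-1, which places new nucleosomes behind the replication fork and is encoded by Chaf1a. Embryos injected with control siRNA served as the reference. Each array carried amplified RNA from 10 embryos. There were 3 control arrays (siControl) and 5 knockdown arrays (P150KD), and their number limits the precision of every value. Between 50.1% and 55.9% of the spots of an array were well above background, the 75th percentile of the processed signal ran from 986 on siControl replicate 3 to 1539 on P150KD replicate 5, and no spot was saturated. The labels call the arrays replicates and do not say whether they hold embryos of separate collections, so the p-values measure the spread between these samples. All levels below are log2 signals relative to the 75th percentile of the array.

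The siRNA target was measured first. The Chaf1a probe stood at 2.25 ± 0.16 (SD, n = 3) in siControl and at -0.62 ± 0.85 (SD, n = 5) in P150KD, a 7.34-fold lower signal (log2 fold change -2.88, SE 0.48, limma adjusted p = 0.0107). The 5 knockdown arrays read -1.47, 0.52, -0.48, -1.45 and -0.23, each below the lowest control array at 2.09. Chaf1b, the middle subunit of CAF-1, fell as well, from 4.79 ± 0.005 to 3.89 ± 0.22 (log2 fold change -0.90, SE 0.18, adjusted p = 0.0188). With the slide column as a block, which leaves 1 knockdown array beside the 3 controls, the Chaf1a difference was -3.72 with an adjusted p of 0.0509.

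**Figure D1:**
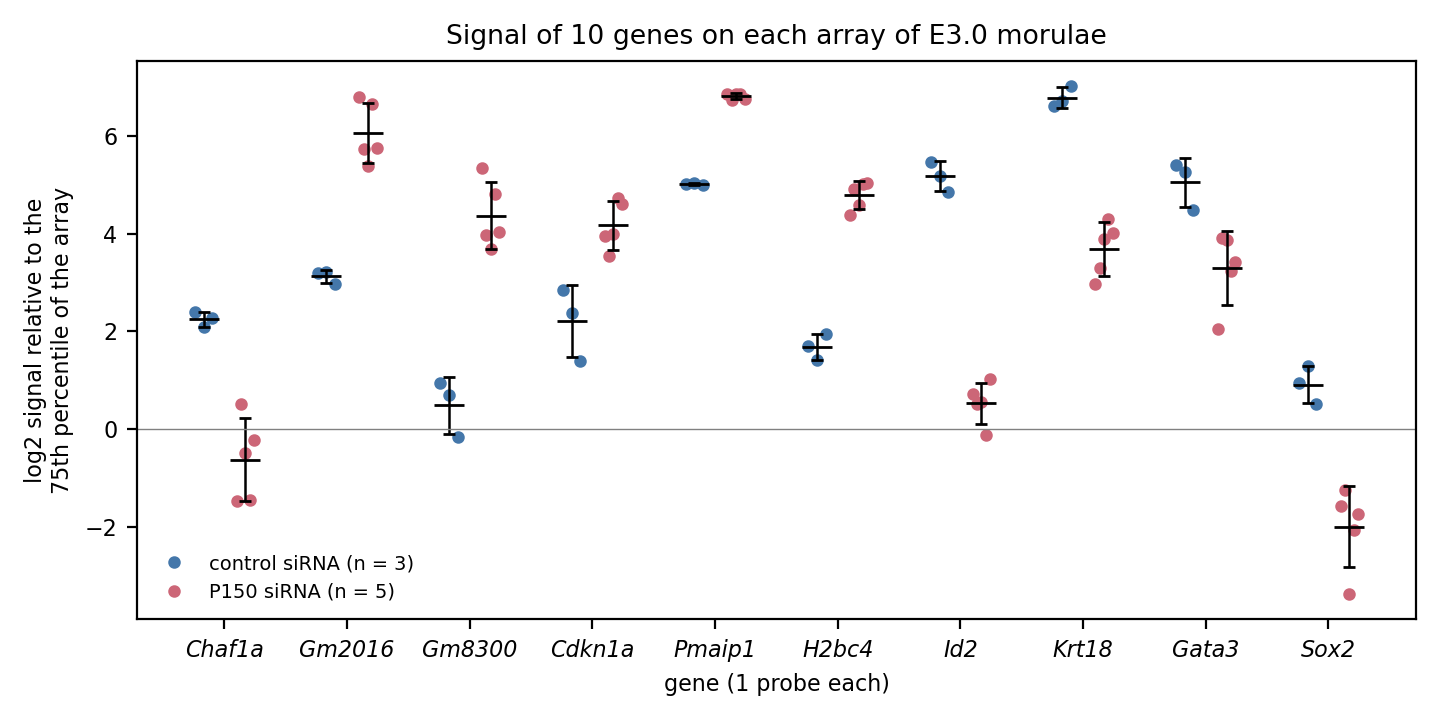
Each point is 1 array, the vertical axis is the log2 signal relative to the array's 75th percentile, and horizontal marks with bars give the mean and SD of control siRNA (n = 3) and P150 siRNA (n = 5) for 10 genes. Chaf1a, Id2, Krt18, Gata3 and Sox2 lay lower on all 5 knockdown arrays than on any control array, and Gm2016, Gm8300, Cdkn1a, Pmaip1 and H2bc4 lay higher.

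The comparison of P150KD with siControl asks which transcripts change when the embryo reaches the morula stage with little P150. In the knockdown morulae 15 of 25 genes of the 2-cell stage rose, as did 10 of 31 p53 targets, 7 of 25 interferon-related genes, 6 of 26 germline genes and 17 of 42 replication-dependent histone genes. Falls were seen in 11 of 25 trophectoderm genes, 13 of 39 DNA replication genes and 23 of 80 oxidative phosphorylation genes. As whole lists, the interferon and DNA replication genes passed with an estimated correlation (camera adjusted p = 0.045 for both), and the other 6 did not, with adjusted p from 0.0504 to 0.279. The fatty acid elongase gene Elovl3 rose at least 1408-fold, and Id2, an inhibitor of helix-loop-helix transcription factors and an early trophectoderm gene, fell by 4.64 on the log2 scale (SE 0.29). Of 30348 probes tested, 4231 (13.9%) changed at a limma adjusted p under 0.05, of which 1907 rose and 2324 fell. At least 2-fold changes made up 1673 of the rises and 1558 of the falls. Counted with 1 probe per gene, 971 of 14601 genes rose and 1527 fell.

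Among genes that were not well above background on any control array, only a nominal lower bound of the rise can be given, set by the lowest signal that counted as well above background. The signal needed to count differs between probes, so these bounds are not exact. Elovl3 was the largest, with a mean of 5.31 ± 0.30 (n = 5) in P150KD (adjusted p = 1e-06). Akr1c21, a hydroxysteroid dehydrogenase gene, rose at least 187-fold, the deubiquitinase gene Usp17lb at least 186-fold, Csrnp3 at least 117-fold and Slc32a1, the vesicular transporter of inhibitory amino acids, at least 102-fold. The adhesion receptor genes Adgrf1 and Adgrb3 rose at least 99.4-fold and at least 59.8-fold, and the glutathione peroxidase gene Gpx6 at least 46.7-fold. A second selection, added after the values were seen, took genes well above background on at least 1 array of each group. Its largest rises were those of Jhy (log2 fold change 8.39, SE 0.71), Acp7 (7.55, SE 0.88), the interferon gamma gene Ifng (7.52, SE 1.66), Rcsd1 (7.46, SE 0.68) and the T cell costimulation gene Cd86 (7.44, SE 0.73). Next came Ptafr, the receptor of platelet-activating factor (7.28, SE 1.11), the Y-linked spermatid gene Sly (7.17, SE 1.04), Ankrd1 (7.13, SE 0.74), Gm12789 (7.02, SE 1.16) and the growth factor gene Bmp2 (6.89, SE 1.44). Of these 10, Ptafr was well above background on 2 control arrays and the other 9 on 1, so the sizes of these folds depend on values near the floor.

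The largest falls reached the floor too. Serpinb6b fell at least 16.7-fold, Vat1l at least 16.0-fold, the T-box gene Tbr1 at least 14.6-fold, Cfc1, a co-receptor of Nodal, at least 12.8-fold, and Ly6g6d and Spink10 at least 9.38-fold each, none of them well above background on any knockdown array. Among genes measured in both groups, Pdzk1 had a log2 fold change of -6.03 (SE 1.39), Fbxo4 of -5.81 (SE 1.03), Cdon of -5.51 (SE 1.41), and Fosl2 of -5.41 (adjusted p = 0.0197). Tmem98 had one of -4.92 (SE 1.18), Klf15 of -4.90 (SE 1.24), P2ry2 of -4.72 (SE 1.05) and Rem1 of -4.56 (SE 1.13). Each of these 8 was measured on only 1 to 3 of the 5 knockdown arrays. Otx2, a homeobox gene of the early embryo, and Id2 were measured on all 8 arrays. Otx2 went from 4.53 ± 0.26 to -0.20 ± 1.15 (adjusted p = 0.00549) and Id2 from 5.18 ± 0.31 to 0.53 ± 0.42 (adjusted p = 4.27e-04).

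Direction and size of the total have limits. The median log2 fold change of all tested genes was -0.24, so a gene list is set against the other genes in what follows. This shift differed with signal level: the 1461 dimmest genes had a median of 0.06, with 40 risen and 41 fallen. For the 1460 brightest the median was -0.28, with 50 risen and 221 fallen. Lists of bright genes are therefore set against many dimmer genes that shifted less. Against 10000 random lists matched on level, the DNA replication median lay at percentile 0.38, oxidative phosphorylation at 0 and ribosomal proteins at 31.6. With quantile normalization 2073 probes rose and 1485 fell, 58.3% risen in place of 45.1%, and scaled to the housekeeping list 3424 rose and 574 fell, 85.6% risen, with the median of all genes at 0.26. Scaling to the housekeeping list subtracts 1 value per array. It therefore moves the fold change of every gene by the same amount and leaves a list's difference from the other genes as it was. Of 713 changed probes 271 fell with the slide column as a block. Leaving out siControl replicate 1, 2 or 3 lowered the total to 1706, 2256 or 2172 probes, and leaving out P150KD replicate 1 or 4 lowered the falls to 1485 or 1510.

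The 2-cell stage and MERVL-linked genes, which are active when the embryo's own genome is first switched on and several of which are driven by retrotransposon repeats, showed the largest shift of any list. All 25 tested members had higher signals in P150KD, 15 rose past the threshold, 0 fell, and 21 rose when adjusted over the list alone. Their median log2 fold change was 2.94, and their mean lay 3.66 above that of the other genes (camera adjusted p = 2.43e-14). The adjusted p was 0.0972 with an estimated correlation. Besides Usp17lb, its relative Usp17la rose from -3.09 ± 0.95 to 2.15 ± 0.77 (adjusted p = 0.00295), Gm8300 from 0.49 ± 0.58 to 4.37 ± 0.69 (adjusted p = 0.00377) and Gm2016 from 3.13 ± 0.14 to 6.06 ± 0.62 (adjusted p = 0.00444). The brightest Zscan4c probe differed by 8.08 (SE 2.39) and did not pass (adjusted p = 0.0631); its other 2 probes had adjusted p of 0.057 and 0.0746. Many members are near-identical copies whose probes can share signal, so their number is not a number of independent genes.

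Of 32 tested oocyte and maternal-effect genes, 4 rose and 0 fell, 4 of them adjusted over the list alone (median 0.73, camera adjusted p = 9.05e-04; adjusted p = 0.045 with an estimated correlation). The zona pellucida gene Zp3 rose from -0.59 ± 0.12 to 2.01 ± 0.41 (adjusted p = 0.00244), Khdc1b from 2.75 ± 0.32 to 5.33 ± 0.46, Fbxw15 by 4.88 on the log2 scale (SE 1.27) and Zar1l at least 6.41-fold. Of 26 germline genes, 6 rose and 0 fell, 11 adjusted over the list alone (median 0.62, camera adjusted p = 5.17e-04; adjusted p = 0.111 with an estimated correlation). Tex101 rose from 0.86 ± 0.85 to 4.03 ± 0.39 (adjusted p = 0.00483), Sycp1, which encodes a part of the meiotic synaptonemal complex, from -0.50 ± 0.66 to 2.56 ± 0.51 (adjusted p = 0.00487), Tuba3a by 1.43 (SE 0.24) and Tex15 by 4.46 (SE 0.96). Of 9 tested sperm markers, a separate list, 0 passed in limma and 3 had an unadjusted p under 0.05; their median was 1.32, and -0.06 with the slide column as a block. The sperm list's adjusted p was 0.279 with an estimated correlation and 0.781 with the slide column as a block.

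Among 31 p53 targets and DNA damage response genes, 10 rose and 0 fell, with 13 risen and 1 fallen adjusted over the list alone (median 0.58, camera adjusted p = 2.57e-07; adjusted p = 0.0972 with an estimated correlation). Pmaip1, the pro-apoptotic gene also called Noxa, rose from 5.02 ± 0.02 to 6.82 ± 0.06 (adjusted p = 0.00109), Gdf15 from -1.56 ± 0.54 to 1.15 ± 0.35, Ei24 from 3.51 ± 0.38 to 5.43 ± 0.18 and Ddit4 from 5.89 ± 0.20 to 7.45 ± 0.20. Cdkn1a, the cell cycle inhibitor p21, was 3.90-fold higher by its brighter probe (log2 fold change 1.96, SE 0.41, adjusted p = 0.0211) and did not pass by the dimmer one (0.39, SE 0.60, adjusted p = 0.695). In limma 21 members did not pass, among them Mdm2 (0.37, adjusted p = 0.192), Bax (0.20, 0.443) and Fas (-2.08, 0.376). Signals were higher for 24 members and lower for 7. The activity of p53 itself was not measured.

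In the list of heat shock, unfolded protein and oxidative stress genes, 6 of 22 rose and 0 fell, with 7 risen and 2 fallen adjusted over the list alone (median 0.08, mean 0.67, camera adjusted p = 0.0413; adjusted p = 0.166 with an estimated correlation). The 4 members with the smallest p belong to the response to unfolded protein and amino acid shortage. Chac1 rose from -1.99 ± 0.35 to 3.78 ± 0.54 (adjusted p = 4.26e-04), Herpud1 by 1.83 (SE 0.29), Dnajb9 by 1.74 (SE 0.27) and the asparagine synthetase gene Asns by 1.19 (SE 0.20). Trib3 rose too, by 2.10 (limma adjusted p = 0.0179). Other members tied to this response did not pass in limma: Hspa5 (0.03, adjusted p = 0.92), Xbp1 (-0.25, 0.52), Ddit3 (0.41, 0.354), Atf3 (2.36, 0.298) and Atf4 (0.68, 0.0501). The response was not tested as a list of its own. The list's call was lost without siControl replicate 1 (camera adjusted p = 0.0744) or without P150KD replicate 2 (camera adjusted p = 0.0808). Its median was 0.58 when scaled to the housekeeping list and 0.24 with quantile normalization.

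Of 25 tested genes for interferon and viral RNA sensing, 7 rose and 0 fell, 9 adjusted over the list alone (median 1.03, camera adjusted p = 4.24e-05; adjusted p = 0.045 with an estimated correlation). Rsad2, the interferon-induced antiviral gene viperin, rose at least 42.6-fold to 0.26 ± 0.73 (n = 5). Ifitm3 rose by 3.16 (SE 0.31), Zbp1, a sensor of viral nucleic acids, by 2.25 (SE 0.35) and Ifitm2 by 1.46 (SE 0.21). A further 8 members, among them Ifit1 and Irf7, were too dim to be tested. The immune genes Ifng and Cd86 rose beside this list, as did 3 of 8 tested leukocyte markers (Coro1a, Srgn and Cd74).

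The trophectoderm list holds genes of the outer lineage that forms the placenta. Of 25 tested members 11 fell and 1 rose, with 15 fallen and 3 risen adjusted over the list alone (median -1.18, and -0.68 when scaled to the housekeeping list, mean difference from the other genes -1.13, camera adjusted p = 6.02e-04; adjusted p = 0.105 with an estimated correlation). Besides Id2, the keratin gene Krt18 fell from 6.78 ± 0.21 to 3.69 ± 0.55 (adjusted p = 0.00295), the fatty acid binding protein gene Fabp3 from 7.25 ± 0.20 to 5.09 ± 0.24 (adjusted p = 0.00201), Dppa1 from 3.15 ± 0.51 to -0.49 ± 0.64 (adjusted p = 0.00364) and the transcription factor gene Gata3 from 5.05 ± 0.50 to 3.30 ± 0.75 (adjusted p = 0.0456). The 1 member that rose, named after its values were seen, was Hand1, a regulator of trophoblast giant cells, from 4.50 ± 0.29 to 5.78 ± 0.30 (adjusted p = 0.0149). Cdx2, the master regulator of the lineage, stood at 4.48 ± 0.04 in siControl and 3.17 ± 1.29 in P150KD and did not pass (adjusted p = 0.247). Its knockdown arrays were split. Replicates 1 to 3 read 1.729, 2.657 and 2.389, while replicates 4 and 5 read 4.505 and 4.546, beside 4.437 to 4.512 on the controls.

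Genes of the inner lineages went in both directions. In the pluripotency and epiblast list 2 of 25 rose and 3 fell, 5 and 4 adjusted over the list alone (camera adjusted p = 0.297). The list's median was 0.12, at percentile 99.52 of random lists matched on level (-0.51 to -0.01), and turned to -0.03 without siControl replicate 3. It was 0.62 when scaled to the housekeeping list and 0.36 with quantile normalization. Sox2 fell from 0.91 ± 0.39 to -2.00 ± 0.83 (adjusted p = 0.0108) and Utf1 had a log2 fold change of -1.28 (SE 0.18), while Klf2 rose by 1.18 (SE 0.18) and Dppa2 by 0.77 (SE 0.16). Pou5f1, which encodes Oct4, differed by -0.46 (SE 0.20, adjusted p = 0.168) and Nanog by -0.62 (SE 0.33, adjusted p = 0.243). In the primitive endoderm list 2 of 16 rose and 2 fell, the same numbers adjusted over the list alone (median -0.16, mean 0.07 and so of the other sign, camera adjusted p = 0.666). That median was 0.34 when scaled to the housekeeping list, 0.05 with quantile normalization, -0.26 without siControl replicate 1 and -0.10 without P150KD replicate 1. Cubn rose by 2.03 (SE 0.20) and Gata4 by 2.25 (SE 0.43), and the basement membrane genes Lamb1 and Col4a1 had log2 fold changes of -1.52 (SE 0.25) and -1.83 (SE 0.41). Gata6 differed by -0.25 (SE 0.22, adjusted p = 0.474).

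Of 39 DNA replication genes 13 fell and 0 rose, 19 adjusted over the list alone (median -0.56, and -0.06 when scaled to the housekeeping list, camera adjusted p = 2.29e-04; adjusted p = 0.045 with an estimated correlation). Fen1, which removes flaps between Okazaki fragments, fell from 6.74 ± 0.09 to 5.58 ± 0.15 (adjusted p = 0.00642), the single-strand binding protein gene Rpa1 from 6.02 ± 0.18 to 5.00 ± 0.10, the ligase gene Lig1 from 4.70 ± 0.03 to 3.52 ± 0.30 and Gins2 from -0.66 ± 0.24 to -1.92 ± 0.32. Of 42 replication-dependent histone genes 17 rose and 0 fell, with 21 risen and 1 fallen adjusted over the list alone (median 1.01, camera adjusted p = 3.84e-09; adjusted p = 0.0504 with an estimated correlation). H2bu2 rose from -1.02 ± 0.36 to 3.12 ± 0.38 (adjusted p = 6.57e-04), H2bc4 from 1.68 ± 0.27 to 4.79 ± 0.29 (adjusted p = 9.53e-04), H3c1 by 2.11 (SE 0.25) and H3c7 by 1.47 (SE 0.18). Histone genes of a class are near-identical in their coding parts, and probes of paralogues can share signal. In the list of cell cycle and mitosis genes 4 of 29 fell and 0 rose, the same adjusted over the list alone (median -0.25, and 0.25 when scaled to the housekeeping list, camera adjusted p = 0.724). The log2 fold change was -1.01 (SE 0.18) for Wee1, -0.64 (SE 0.15) for Cdc25a, -0.92 (SE 0.23) for Birc5 and for Mad2l1 -0.96 (SE 0.26).

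The histone chaperone list did not pass (median -0.04, camera adjusted p = 0.943). Its median lay at percentile 97.85 of random lists matched on level, just above their range of -0.48 to -0.05, and at -0.22 without siControl replicate 3. Of its 26 members 5 fell and 1 rose, 7 and 2 adjusted over the list alone. Besides Chaf1a and Chaf1b, the falls were those of Asf1b, which hands histones to CAF-1 (-0.98, SE 0.19), the replication clamp gene Pcna (-0.99, SE 0.21) and Daxx, a chaperone of histone H3.3 (-0.70, SE 0.16). The oocyte chaperone gene Npm2 rose from -2.07 ± 0.48 to -0.07 ± 0.28 (adjusted p = 0.00557). Of 27 heterochromatin and DNA methylation factors, 7 fell and 3 rose, 10 and 3 adjusted over the list alone (median -0.40, camera adjusted p = 0.531). Dnmt3b, a de novo DNA methyltransferase gene, fell from 6.84 ± 0.09 to 5.51 ± 0.19 (adjusted p = 0.00508), Uhrf1, a recruiter of maintenance methylation, from 5.51 ± 0.12 to 4.12 ± 0.24 (adjusted p = 0.00619) and Mphosph8 from 5.89 ± 0.08 to 4.67 ± 0.31, and Atf7ip rose from 3.58 ± 0.10 to 4.61 ± 0.22. The probes of Dnmt3b went both ways: a dimmer one rose by 1.54 (SE 0.28, adjusted p = 0.0149). When arrays were scaled to the housekeeping list the medians turned to 0.47 for the chaperones (0.15 with quantile normalization) and 0.10 for the heterochromatin factors (-0.18 with quantile normalization). The median of all genes moved by the same amount, to 0.26 when scaled to the housekeeping list.

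The enzymes that place H4K20me3, the histone mark named in the study's title, were followed by their genes. Kmt5c differed by -0.89 (SE 0.29) and did not pass (adjusted p = 0.0812). Kmt5b had 3 probes, each with a higher mean in P150KD, that differed in size and in passing. In limma the brightest differed by 0.34 (SE 0.30, adjusted p = 0.483) and the dimmest by 0.75 (SE 0.30, adjusted p = 0.141). Only the remaining probe passed, with a rise of 1.72 (SE 0.31, adjusted p = 0.0142). Setdb1, which methylates histone H3 at silenced retrotransposons, differed by -0.18 (SE 0.25, adjusted p = 0.656). Of 26 imprinted genes 1 rose and 2 fell, 0 and 2 adjusted over the list alone (camera adjusted p = 0.895). Slc38a4 fell from 4.01 ± 0.29 to 1.96 ± 0.28 and Sfmbt2 from 3.29 ± 0.26 to 1.81 ± 0.54. The brightest Plagl1 probe rose from 1.21 ± 0.65 to 2.75 ± 0.55, while a dimmer Plagl1 probe had a log2 fold change of -1.82 (adjusted p = 0.0116). The imprinted list's median was -0.08, and 0.43 when scaled to the housekeeping list. Probes for retrotransposons themselves were not analysed here.

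Of 80 oxidative phosphorylation genes 23 fell, 1 rose and 56 did not pass, with 50 fallen and 1 risen adjusted over the list alone (median -0.66, and -0.16 when scaled to the housekeeping list, camera adjusted p = 1.09e-08; adjusted p = 0.279 with an estimated correlation). The succinate dehydrogenase genes Sdhb, Sdhc and Sdha had log2 fold changes of -1.33 (SE 0.15), -1.05 (SE 0.16) and -1.05 (SE 0.17), and the tissue-restricted subunit gene Cox7a1 rose by 1.93 (SE 0.30). Of 15 reference housekeeping genes 5 fell and 1 rose, the same adjusted over the list alone (median -0.32, and 0.19 when scaled to their own mean, camera adjusted p = 0.0571). Pgk1 had a log2 fold change of -1.68 (SE 0.23) and B2m of -1.61 (SE 0.25). Sdha fell as above, Actb had one of -1.20 (SE 0.25) and Gapdh of -1.07 (SE 0.23), while the transferrin receptor gene Tfrc rose by 1.41 (SE 0.15). Actb and Gapdh were singled out after their values were seen, because they often serve as the reference in quantitative PCR. Of 84 ribosomal protein genes none passed, at the adjusted threshold, over the list alone or at an unadjusted p under 0.05 (0 genes by limma). The list's median of -0.27 lay near that of all genes, as did its median of 0.23 when arrays were scaled to the housekeeping list (all genes 0.26). Its camera adjusted p was 0.0169; the adjusted p was 0.773 with an estimated correlation, 0.131 without siControl replicate 3, 0.0565 without P150KD replicate 4 and 0.133 without P150KD replicate 5. The housekeeping list passed without P150KD replicate 1 (adjusted p = 0.0443) or 2 (adjusted p = 0.0368).

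Lists of cumulus and sperm cells stood for other cells that embryos can carry, and leukocyte markers were added later. Of 8 tested leukocyte markers 3 rose: Coro1a had a log2 fold change of 2.67 (adjusted p = 0.0146), Srgn of 1.97 (adjusted p = 0.0417) and Cd74 of 2.31 (adjusted p = 0.00808). Of 7 tested cumulus and granulosa cell genes 0 passed, over all genes or over the list alone, and 1 had an unadjusted p under 0.05 in limma (median 0.17, camera adjusted p = 0.381). The cumulus median was 0.67 when scaled to the housekeeping list. Of 9 tested sperm genes 0 passed either way and 3 had an unadjusted p under 0.05 (median 1.32, camera adjusted p = 0.0376; adjusted p = 0.279 with an estimated correlation). Gapdhs, the member with the smallest p, stood at -4.79 in siControl and -2.44 in P150KD (adjusted p = 0.0527). The list did not pass without siControl replicate 2 (adjusted p = 0.0566) or P150KD replicate 3 (adjusted p = 0.0796).

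**Figure D2:**
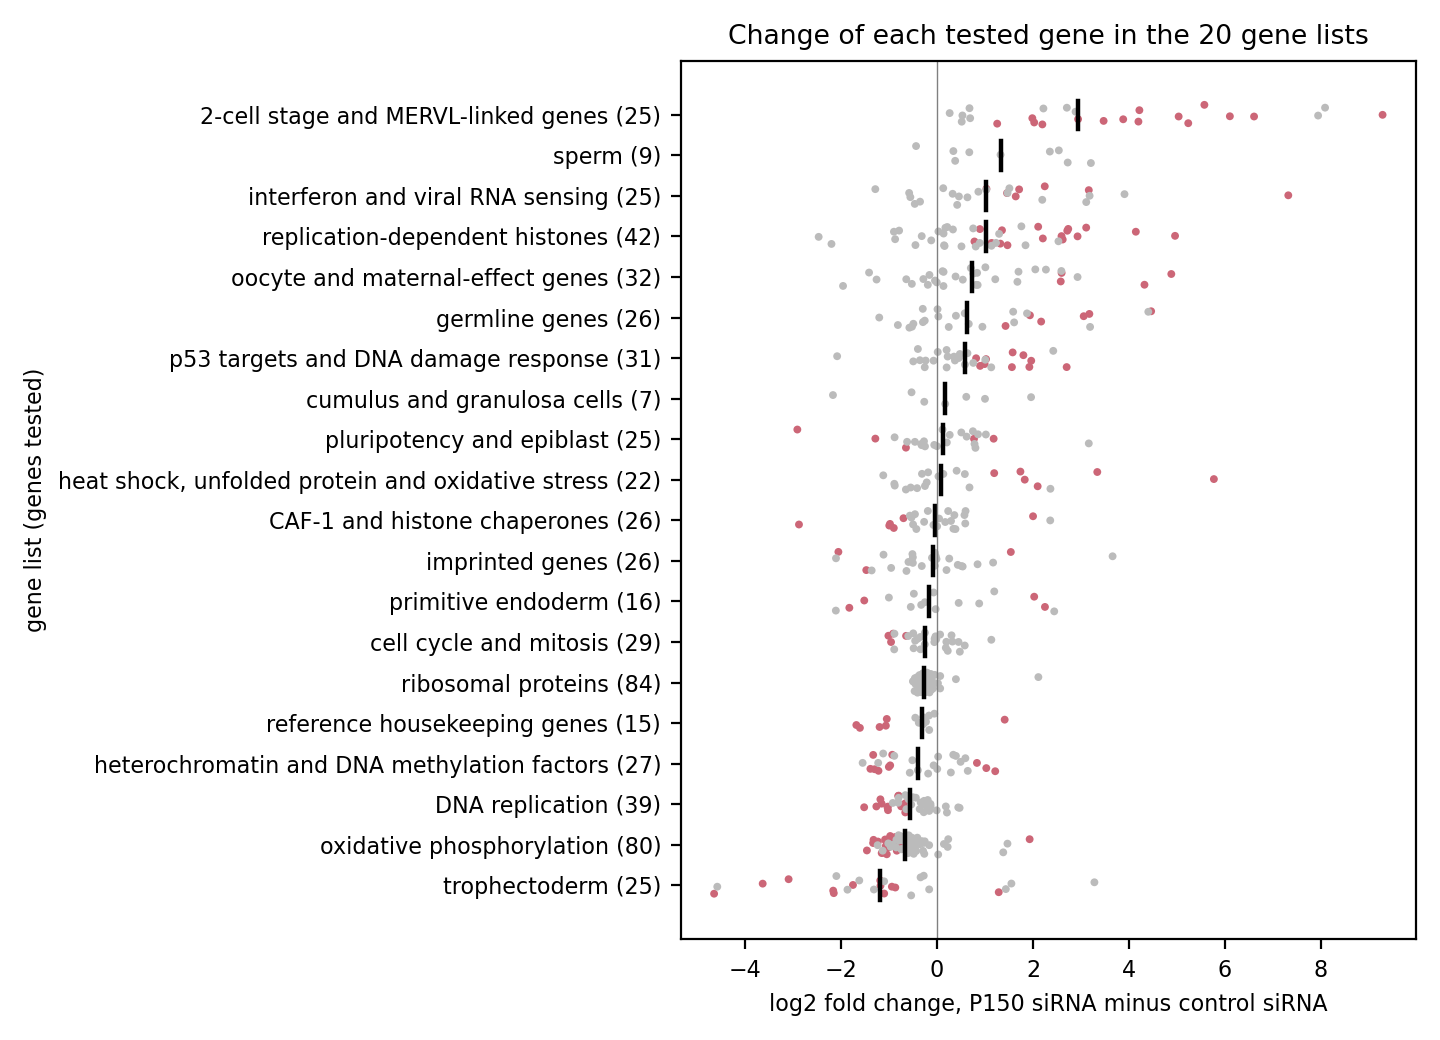
Each point is 1 tested gene, placed by its log2 fold change (P150 siRNA minus control siRNA) on the horizontal axis and by its list on the vertical axis, with the number of tested genes in brackets, red where limma's adjusted p was under 0.05, and a black bar at the list's median. Medians ran from -1.18 in the trophectoderm list to 2.94 in the list of 2-cell stage and MERVL-linked genes.

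Calls of whole lists carry further limits. Of the 20 lists 12 passed with the preset correlation, and 3 of them, those of oocyte, DNA replication and interferon genes, also with an estimated one. In an exact permutation over the 56 splits of the 8 arrays into 3 and 5, no other split gave a mean shift as large as the real one for 9 lists (2-cell, trophectoderm, oocyte, p53, DNA replication, interferon, stress, germline and histone genes; share 0.018 each), while with the real split included 2 splits did for oxidative phosphorylation, 3 for sperm and 21 for ribosomal protein genes. Other splits called up to 11 lists with the preset correlation. Medians moved with the processing as well. Scaled to the housekeeping list, those of the oocyte, p53 and germline lists were 1.23, 1.08 and 1.12. That scaling moves all genes alike (their median was 0.26), so it does not bear on a list's difference from the other genes. Normexp gave 0.40 for oocyte and 0.65 for interferon genes. Without siControl replicate 3 the medians of the oocyte and germline lists were 0.29 and 0.39, and that of the oocyte list was 0.47 without P150KD replicate 1 and 0.38 without P150KD replicate 5. The sperm list's median was 2.31 without siControl replicate 1, 0.48 without siControl replicate 3, 2.38 without P150KD replicate 1, and 0.80 without P150KD replicate 3 or 4. The stress list's was 0.05 without P150KD replicate 5.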

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

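The tests of the 3 patterns were chosen after the main values were seen; those of signal level, leukocytes, slide position and probes gained against lost were set before their own results, and those of the single-copy 2-cell genes, of quantile normalization and of probes looked up on the dimmer arrays after related results. In the 5 knockdown arrays, 10 of 147 values examined had 1 array far from the other 4, measured as its gap to the nearest divided by the whole range; chance gives about 1 in 20. Usp17lb read -0.15 on P150KD replicate 3 and 2.63 to 3.66 on the others (ratio 0.728). Fbxo4 read -3.26 on replicate 5 and -7.43 to -6.26 on the others (0.719). Ly6g6d read -5.24 on replicate 3 and -7.37 to -7.05 on the others (0.847). Ptafr read 2.39 on replicate 5 and 3.27 to 3.47 on the others (0.813). Klf2 read 7.26 on replicate 4 and 6.81 to 6.88 on the others (0.835). Rpl3l read -7.12 on replicate 2 and -3.51 to -2.68 on the others (0.814). H3c7 read -0.55 on replicate 5 and -0.89 to -0.80 on the others (0.743). Ssrp1 read 6.48 on replicate 2 and 6.71 to 6.78 on the others (0.78). Ubn2 read 0.27 on replicate 1 and 1.74 to 2.27 on the others (0.737). On the second principal component, replicate 2 lay at -189.4 and the others at 5.9 to 73 (0.744).

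Among the 56 splits of the 8 arrays into 3 and 5, the real one gave 4231 changed probes. Any other gave at most 43, so only the real split (1 split) gave as many. With 56 splits no stronger result is possible, so the test argues against chance for the total but cannot exclude it. Every other split puts control and knockdown arrays together, so the gap between 4231 and 43 is not a measure of strength. For gene lists past the threshold the real split was also the only one (1 split), with 12 lists against up to 11 in others. That margin is 1 list, and the lists with a shift beyond every other split are named with their values in the account of the lists.

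The rise of the 2-cell stage and MERVL-linked genes was weighed first. A bias tied to signal level is argued against: the median of 2.94 lay at percentile 100 of 10000 random lists matched on level, whose central range was -0.59 to 0.24. Signal shared between near-identical copies stays open for the 19 tested members of multicopy families, whose median was 4.20. The 6 tested members outside such families had a lower median of 0.97, with 3 risen; against all other genes limma camera gave them 0.000139 with the preset correlation and 0.0158 with an estimated one, which says nothing of shared signal in the families. A response to the loss of P150 may account for the rise and stays open as well, untested beyond the comparison itself. Embryos at an earlier point of development when collected could also account for it. The design has no stage other than the morula to tell these apart.

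The fall of the trophectoderm genes was weighed next. A bias tied to signal level is argued against, since the median of -1.18 lay at percentile 0 of the matched random lists, with a central range of -0.61 to 0.06. Scaling between arrays that differs with signal level is argued against too. With quantile normalization the list's camera adjusted p was 0.000601 at the preset correlation, its median -0.97 and that of all genes -0.12. In the main normalization the camera adjusted p was 0.105 with an estimated correlation. A shift shared by all genes of an array cancels when a list is set against other genes, so camera cannot test it. The fall could reflect P150 knockdown or embryos at an earlier point of development when collected, and the design has no stage other than the morula to tell these apart.

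The last pattern is the set of 196 probes above background on all 5 knockdown arrays and on no control array, against 85 the other way round. Stronger signal on the knockdown arrays was not decided: P150KD replicates 2 and 3 had fewer spots above background (50.1% each) than any control, so their ratio of probes gained to lost (smallest 0.47) only restates that, and of 469 probes gained on the other 3 arrays 41.8% were above background on both, short of the 50% set as the bound against it, though 1% of the remaining probes dark in the controls were. Leukocytes, a candidate source for Cd86 and Ptafr, are argued against where they carry Ptprc, Lyz2, Tyrobp, Laptm5 and S100a8, which were above background on no knockdown array. Of 15 markers 8 could be tested and 3 of these rose (Coro1a 2.67, Srgn 1.97, Cd74 2.31), Itgb2 differed by 1.88 without passing (adjusted p = 0.0953), and 6 were above background on all 5 knockdown arrays, among them Lcp1 of the trophectoderm list. Position on the slide stays open because only 1 knockdown array shares a column with the controls, though its values go against the column as the whole cause: on it, 81.7% of 240 probes gained on the other 4 were above background, against 7.8% of the remaining probes dark in the controls, and with the column as a block 592 of the 4231 changed probes kept their call.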

How the results depend on the processing

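The slide column block and scaling to the housekeeping list were chosen after the data were seen. Of the 4231 changed probes, 0 took the opposite direction in limma under any alternative that tested them. These probes had been picked for their difference on the same arrays that the alternatives refit, so a kept direction is no independent evidence. With the replicate number as a block 0 probes changed, 0 up and 0 down, with 6371 at an unadjusted p under 0.05; that fit leaves 2 residual degrees of freedom, and the numbers do not pair the arrays (across probes, deviations from the group means correlate at r -0.014, -0.075 and -0.017 between arrays of one number). With the slide column as a block 713 changed, 442 up and 271 down. Scaled to the housekeeping list, 3424 rose and 574 fell, with the median of all genes at 0.26. Quantile normalization gave 1485 falls and scaling to the median 1511. Leaving out 1 array gave 1706 to 3749 changed probes, 1016 to 1770 risen and 690 to 1979 fallen, the lowest without siControl replicate 1. Chaf1a did not pass with the replicate block (log2 fold change -2.73, SE 0.55, against -2.88, SE 0.48; adjusted p = 0.163) or the slide column block (-3.72, SE 0.69; 0.0509), and passed with each array left out in turn (0.0075 to 0.0454). Of 142 other named genes 101 had a call; all 101 lost it with the replicate block, 61 with the slide column and 29 without siControl replicate 1.

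Among lists, an estimated correlation ended the calls of the trophectoderm (0.105), 2-cell (0.0972), p53 (0.0972), stress (0.166), germline (0.111), sperm (0.279), ribosomal (0.773), oxidative phosphorylation (0.279) and histone lists (0.0504). With fry, the chaperone (0.00191), heterochromatin (0.00404), cell cycle (0.00408), imprinted (0.00164) and housekeeping lists (0.00373) passed, and the sperm (0.0704) and ribosomal lists (0.0951) did not. The stress list did not pass with the replicate block (0.0736) or the mean of all probes (0.0535), and ranged from 0.0257 to 0.0808 without 1 array. The sperm list did not pass with normexp (0.0846), quantile normalization (0.0991), array weights (0.0543) or the slide column (0.781), and ranged from 0.01 to 0.0796 without 1 array. The housekeeping list passed with no filter (0.0189) and with trend and robust (0.0344), and ranged from 0.0368 to 0.111. The ribosomal list did not pass with quantile normalization (0.995), scaling to the median (0.0691), probes above background on all 8 arrays (0.0957), the replicate block (0.826), the mean of all probes (0.0763) or the slide column (0.937, median -0.11), and ranged from 0.00358 to 0.133. The cause was not tested, except that blocks and left-out arrays leave fewer degrees of freedom. The slide block was not run (1 slide), nor were the alternatives for retrotransposon probes, which could not be identified. Dim genes are limited by signal over background: 50.1% to 55.9% of spots were well above it.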

Other observations

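The tests in this paragraph were chosen after the values were seen. Grouped by the stem of their symbols, 171 families had at least 10 tested genes. Of 12 Speer genes, a testis-expressed family, 11 rose and 0 fell (median log2 fold change 2.65, camera adjusted p = 5.06e-09), and of 26 Pramel genes, a family active in germ cells and early embryos, 15 rose and 0 fell (median 1.36, adjusted p = 7.72e-07). Genes of the mitochondrial ribosome were lower. Of 48 Mrpl genes 18 fell (median -0.69, camera adjusted p = 7.72e-07), and of 29 Mrps genes 12 fell (median -0.78, camera adjusted p = 3.91e-04). Mrpl and Mrps genes were not compared with genes of like level. None of the families passed with an estimated correlation, the smallest adjusted p being 0.411, and near-identical Speer and Pramel copies can share signal. Of 133 olfactory receptor genes 26 rose and 1 fell (camera adjusted p = 0.00267; adjusted p = 0.672 with an estimated correlation). Their median of 0.12 lay at percentile 87.41 of random lists matched on level (-0.25 to 0.25), which argues against a rise of the family as a whole beyond genes of like level and leaves a rise of some members open.

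Neighbouring genes were tested by a choice made before the result was seen. Of 13513 pairs of adjacent tested genes, with pairs of one name family left out, 89 had both genes risen, against a median of 59 in permutations among genes of like level (46 to 74, permutation p = 1e-04, the smallest that 10000 permutations can give). Both had fallen in 186 pairs, against a median of 157 (135 to 179, permutation p = 0.0051). These values are consistent with changes shared by neighbouring genes, though overlapping transcripts and unnamed gene families were not ruled out. Of 5866 tested probes for unnamed genomic intervals, 280 rose and 175 fell. Of all 30348 tested probes 1907 rose and 2324 fell, a larger share in both directions, so the interval probes changed less often than probes in general.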
